A study of Mus musculus with 4 samples.

How the data were processed

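RNA was sequenced from CD11c+ cells of mouse mesenteric lymph nodes after 6 h of culture. CD11c is an integrin found on dendritic cells and on some other leukocytes, and the cells were enriched with magnetic beads, so other lymph node cells can remain. Per the labels' protocols, the nodes of wild-type C57BL/6J mice were pooled, the enriched cells of each pool were divided between a well with water and a well with 10 µM of an Ffar2 agonist, and libraries were made with the SMART-seq v4 kit for very low RNA input. The agonist's chemical name was not given in the sources used here. Groups and replicate numbers were taken from the sample titles, which gave 2 control and 2 agonist libraries, both groups numbered 2 and 3.

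Each deposited file holds whole-number read counts per gene, made by the authors and not normalized. Per the submitters' processing notes, STAR 2.7, HTSeq 0.11.1 and the mouse build GRCm38 (mm10) were used. The strand setting of the counting was not given in the sources used here. The kit does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. All 55450 gene rows carried an identifier and symbol found in the GENCODE M21 annotation, which supplied the coordinates on GRCm38. Summary lines that name no gene were left out of library sizes and tests. Reads outside annotated genes made up 15.96% to 19.99% of each library's reads, reads overlapping several genes 5.77% to 6.50%, and reads aligned to more than 1 place 6.54% to 6.99%. Such reads were not counted for any gene, so near-identical genes such as immunoglobulin segments and the classical major histocompatibility genes can be undercounted.

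The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept with the default expression filter of edgeR (minimum count 10), which left 18297 genes. Library sizes were scaled by trimmed mean of M-values (TMM), with factors of 0.947 to 1.05. The agonist was compared with the control by the two-sided quasi-likelihood test with group as the only term, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are log2 values of agonist over control. Their standard error (SE) was derived from the log2 fold change and the F statistic of the test. Intervals are 95% intervals built from that SE, with the same degrees of freedom for all genes. CPM values are counts scaled to a common library size with TMM factors. A prior count of 2 was used for log2 CPM of single libraries. Figures were drawn with matplotlib 3.10.9, and tests of explanations used Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3.

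Before the files were opened, 30 gene lists with 657 entries were fixed for dendritic cell functions, signalling, metabolism and the markers of cell types that the enrichment can hold. Every entry matched a gene row. Lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. The genes named for the agonist comparison follow a rule fixed at the same time. It takes Ffar2, Il27 and Ebi3, then the 10 genes with the largest rise and the 10 with the largest fall past the threshold that had an average log2 CPM of at least 2 and the same direction in both pools. Predicted, mitochondrial and antigen receptor segment genes were excluded from that part, and where too few genes passed, those with the smallest unadjusted p filled the places. From each described list, up to 4 members with the smallest p were eligible. Genes named for the comparison of the pools, and genes outside these rules, were chosen after their values were seen.

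The protocol states that the cells of a pool were divided between the wells, and the numbers in the titles pair the libraries. Libraries with the same number deviated together from their group means (Pearson r = 0.288 across 18297 genes). Both libraries numbered 2 had Xist reads and both numbered 3 had reads of Y-linked genes. A fit with the pool as a block was therefore set beside the unblocked one. A pool holds the cells of several nodes, so p-values of single genes in the unblocked agonist comparison measure the spread between pools and wells. The comparison of the pools has 1 pool per arm, so its p-values of single genes measure the spread between wells only. Camera at the preset correlation sets the members of a list against all other genes. Its p-values therefore rest mainly on the spread between genes, with that correlation assumed, and not on that between pools or wells.

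The fits were tested on counts simulated from the means, dispersions and library sizes of these libraries, with 17348 genes tested. In the agonist comparison without the block, 0 of 67 genes changed 2-fold, 16 of 67 changed 4-fold and 56 of 66 changed 8-fold were recovered, with 0 false calls. With the block the recovered numbers were 19 of 67, 64 of 67 and 66 of 66, with 13 false calls beside the changed genes and 2 in counts simulated with no effect. A list given a shift larger than the median of any list called below was recovered in both fits, with 0 other lists called. Each gene was simulated on its own, so the simulated lists held no correlation between genes. The T cell list of the real data had an estimated correlation of 0.828 in the unblocked fit. It was -0.0421 in the fit with the block, which takes out the difference between the pools. The simulation therefore cannot tell how often camera calls lists falsely here. Alternatives covered other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom, the block, other list tests and leaving out each library. Intervals come from the fit and so include the estimated spread between libraries, while the floors given for genes without reads cover counting error only.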

Results

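The series title links Ffar2, a G-protein-coupled receptor for short-chain fatty acids, with IL-27 made by dendritic cells. The data address what an Ffar2 agonist did to the transcripts of CD11c+ mesenteric lymph node cells within 6 h. There were 2 control libraries (water) and 2 agonist libraries (10 µM), made from 2 pools of cells that were each divided between the conditions. Reads assigned to genes numbered 43238375 in control replicate 2, 52417584 in control replicate 3, 49509736 in agonist replicate 2 and 59902172 in agonist replicate 3. Between 23225 and 23770 genes had at least 1 read in a library.

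Ffar2 itself was read at a low level in both conditions. The gene (ENSMUSG00000051314.11, chromosome 7, 30818348 to 30823775, GRCm38) had 176 and 202 reads in the control libraries and 89 and 116 in the agonist libraries. Its level was 3.96 ± 0.124 CPM (SD, n = 2) in the control and 1.88 ± 0.236 CPM (SD, n = 2) in the agonist wells, lower in both pools. The log2 fold change was -1.07 (SE 0.47, 95% interval -2.20 to 0.05), and edgeR's quasi-likelihood test gave an unadjusted p of 0.0587 and an adjusted p of 0.9999, so the difference did not pass the test. With the pool as a block the log2 fold change was -1.08 (SE 0.46, unadjusted p = 0.043, edgeR adjusted p = 0.9998).

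Il27, which encodes the p28 subunit of IL-27 (ENSMUSG00000044701.5, chromosome 7, 126589010 to 126594941), had 47 to 60 reads per library. Its level was 1.01 ± 0.160 CPM (SD, n = 2) in the control and 1.07 ± 0.118 CPM (SD, n = 2) in the agonist wells. The log2 fold change of 0.08 (SE 0.62, 95% interval -1.42 to 1.58) lay within the spread between libraries (edgeR adjusted p = 0.9999), and turned to -0.0012 without agonist replicate 2. Ebi3, the gene of the other IL-27 subunit (ENSMUSG00000003206.7, chromosome 17, 55952640 to 55957022), had 14.1 ± 2.79 CPM in the control and 17.5 ± 4.16 CPM in the agonist wells (SD, n = 2). Its log2 fold change was 0.31 (SE 0.36, 95% interval -0.56 to 1.17), and its edgeR adjusted p was also 0.9999. A change of Il27 of a size within that interval is not ruled out. Of the 11 genes of IL-12 and IL-27 family cytokines and receptors, 10 were tested and 0 passed, and adjusted over the list alone the count was also 0. Among them Il6st, the shared signalling receptor gp130, had a log2 fold change of 0.34 (SE 0.29) and Il27ra, the IL-27 receptor subunit, one of -0.30 (SE 0.32). The list median was -0.04 and its mean 0.01, and camera gave an adjusted p of 0.753.

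**Figure D1:**
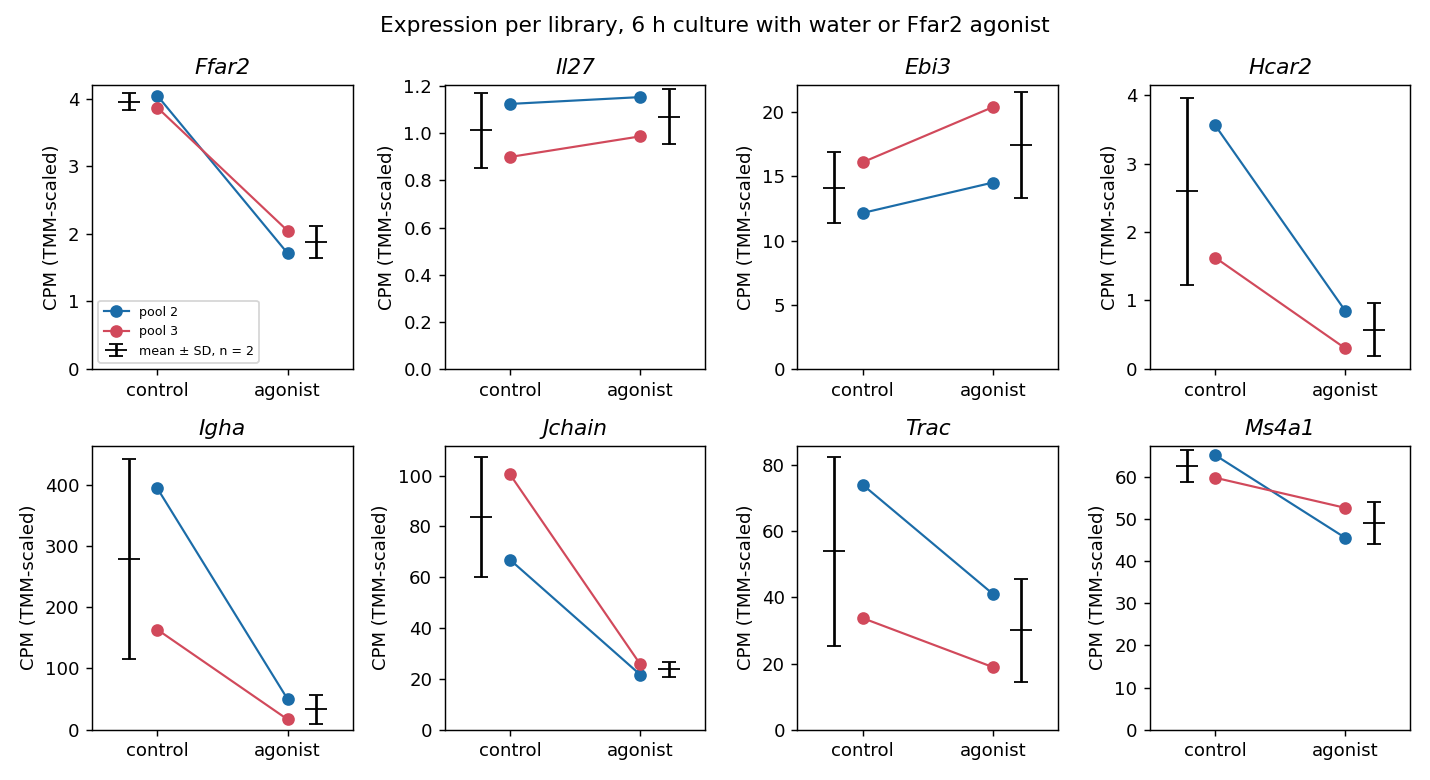
CPM (TMM-scaled, linear axes from 0) of 8 genes in each library, with lines joining the control and agonist wells of a pool and bars giving the mean and SD of 2 libraries. Ffar2 (control 4.04 and 3.87 CPM, agonist 1.71 and 2.05 CPM) and Igha were lower in the agonist well of both pools, and Il27 lay between 0.90 and 1.15 CPM in the 4 libraries.

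Over all genes, the agonist comparison gave 0 genes past the threshold in edgeR's quasi-likelihood test of 18297 genes. At an unadjusted p under 0.05 there were 117 higher and 172 lower genes, 289 in all, limma-voom called 0 genes and DESeq2 called 7. The balance at that unadjusted p depended on the fit. It was 309 higher and 336 lower in edgeR with the pool as a block, 223 and 169 in DESeq2, and 511 and 263 in DESeq2 with the block. With the pool as a block edgeR called 1 gene, Igha, the constant region of IgA (chromosome 12, 113254830 to 113260236). Igha had 394 and 164 CPM in the control libraries and 50.04 and 16.8 CPM in the agonist libraries. It fell by 3.13 on the log2 scale in the blocked fit (SE 0.26, adjusted p = 0.0140), against a log2 fold change of -3.06 (SE 0.66, adjusted p = 0.9999) without the block. The blocked call was lost with a stricter filter (adjusted p = 0.109), and without the block Igha was among 9 genes called with no filter (adjusted p = 0.00251). When each library was left out of the unblocked fit, 0 to 2 genes were called, none of them Igha and all of them other immunoglobulin genes. Of the 7 genes called by DESeq2, Igha, Jchain and the variable segments Igkv8-27, Igkv19-93 and Ighv1-12 were lower and Mcpt4 and Retnla were higher. Reads of immunoglobulin segments can be shared between near-identical copies, so these values are uncertain.

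None of the 20 genes that filled the places of largest rise and fall passed the threshold in edgeR, and each had an adjusted p of 0.9999. Jchain, the joining chain of polymeric IgA and IgM (chromosome 5, 88519809 to 88527891), was the first of the lower genes, with 83.7 ± 23.7 CPM in the control and 23.7 ± 2.94 CPM in the agonist wells (SD, n = 2) and a log2 fold change of -1.82 (SE 0.33). In the blocked fit Jchain had a log2 fold change of -1.79 (SE 0.27, edgeR adjusted p = 0.477). Other lower values were -1.51 (SE 0.44) for Il1rl2, the IL-36 receptor, -1.42 (SE 0.44) for the ion cotransporter gene Slc12a2, -1.08 (SE 0.39) for Ube2t and -0.91 (SE 0.33) for Mpeg1, which encodes perforin-2 and whose value was -0.43 without control replicate 3. Ttn, Hist2h2be, Anp32a, Smyd4 and Nhsl2 completed that group with values from -1.28 to -0.84. Higher values were 1.13 (SE 0.38) for Rab3il1, which encodes a Rab exchange factor, 1.05 (SE 0.38) for the AMP deaminase gene Ampd3, 0.88 (SE 0.29) for the splicing factor gene Smndc1 and 1.28 (SE 0.45) for Disp1. Ippk, Bicral, Atad5, Snx33, Ccdc84 and Zfp101 had values between 0.88 and 1.05. In simulated counts of this design the unblocked test recovered 0 of 67 genes changed 2-fold and 16 of 67 changed 4-fold, so changes of these sizes were mostly out of its reach. The test with the pool as a block recovered 19 of 67 and 64 of 67, with 13 false calls beside them. None of the 20 genes passed in the blocked edgeR fit of the real data either.

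Among 24 genes of short-chain fatty acid receptors and G-protein signalling, 22 were tested and 0 passed, over all genes or adjusted over the list alone. Hcar2, the receptor for niacin and the ketone body beta-hydroxybutyrate, had 155 and 85 reads in the control and 44 and 17 reads in the agonist libraries. Its log2 fold change was -2.18 (SE 0.77, unadjusted p = 0.0294, edgeR adjusted p = 0.9999). With the pool as a block it was -2.24 (SE 0.59, unadjusted p = 0.0043, edgeR adjusted p = 0.9998). Gna13 had a log2 fold change of 0.48 (SE 0.26). The list median was -0.03, with a camera adjusted p of 0.753.

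Of the 30 gene lists, 4 passed camera at the preset correlation, and 0 passed with an estimated correlation or with fry. With the pool as a block 7 passed, again 0 with an estimated correlation. The test with an estimated correlation could hardly pass with so few libraries, so its p-values below weigh neither for nor against a call. Across all lists 0 members passed over all genes in the unblocked fit. Adjusted over the list alone 2 did, Jchain (adjusted p = 0.0151) and Igha (adjusted p = 0.0193) in the plasma cell list, both lower.

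T cell marker genes fell as a group in the agonist wells. The median log2 fold change of the 20 members was -0.56, with -0.46 in pool 2 and -0.75 in pool 3, and 16 of 20 were lower in both pools (camera adjusted p = 2.77e-05, adjusted p = 0.831 with an estimated correlation). With the pool as a block the median was -0.61 (camera adjusted p = 4.17e-11, adjusted p = 0.893 with an estimated correlation). The correlation estimated in the blocked fit was -0.0421, so correlated members do not account for that adjusted p of 0.893. No member passed on its own. Trac, the T cell receptor alpha constant region, had a log2 fold change of -0.85 (SE 0.52), Cd247, the CD3 zeta chain, one of -0.75 (SE 0.36) and Cd8b1 one of -0.54 (SE 0.34). The call was lost without control replicate 2 (median -0.08, adjusted p = 0.634) and without agonist replicate 3 (median -0.10, adjusted p = 0.939), fits in which the pools are unequal between the groups and the difference between the pools enters. B cell marker genes also fell as a group, with a median of -0.26 over 17 members and 13 lower in both pools (camera adjusted p = 0.0496, adjusted p = 0.831 with an estimated correlation). Cd22, an inhibitory B cell receptor, had a log2 fold change of -0.55 (SE 0.37), and Ms4a1, which encodes CD20, one of -0.35 (SE 0.27). Without control replicate 2 or without agonist replicate 3 the test of the B cell list pointed the other way (adjusted p = 0.781 and 0.939). The B cell call was also lost with DESeq2 size factors (adjusted p = 0.0524), total counts only (0.0805) and no filter (0.0663).

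In the blocked fit the markers of plasmacytoid dendritic cells (median -0.23, camera adjusted p = 0.0131) and of NK cells (median -0.26, adjusted p = 0.0283) fell as groups too, with an adjusted p of 0.893 for each with an estimated correlation. Without the block their adjusted p values were 0.139 and 0.112. Siglech, a plasmacytoid dendritic cell lectin, had an unblocked log2 fold change of -0.53 (SE 0.46), which turned to 0.01 without control replicate 2 (a value that includes the difference between the pools), and Gzmb, a cytotoxic granule protease, one of -1.70 (SE 0.85). The plasma cell list was called lower with the block (adjusted p = 0.00531, 0.893 with an estimated correlation; unblocked adjusted p = 0.258), although its blocked median was 0.21 and its mean -0.11. Of its members, Igha and Jchain alone passed when adjusted over the list. Markers of both classes of conventional dendritic cells were not called (adjusted p = 0.360 and 0.808), with medians of 0.10 for the cDC1 and -0.09 for the cDC2 list. Lists for monocytes and macrophages, neutrophils, and stromal and endothelial cells were not called either, with adjusted p values of 0.980, 0.666 and 0.888.

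Target and feedback genes of NF-kB, a transcription factor of inflammatory activation, were called higher by camera, with a median of 0.14 over 25 members and only 11 higher in both pools (camera adjusted p = 0.0413, adjusted p = 0.831 with an estimated correlation). The median was 0.01 in pool 2 and 0.20 in pool 3. Nfkb2 had a log2 fold change of 1.02 (SE 0.40), with 1.78 in pool 2 and 0.23 in pool 3, and the inhibitor gene Nfkbia one of 0.87 (SE 0.43), with 1.79 and 0.04. Many abundant genes were higher in agonist replicate 2 than in control replicate 2 (75 of 1542 by more than 1 log2 unit, against 0 in pool 3). In 67 of the 75, control replicate 2 was the lowest and agonist replicate 2 the highest of the 4 libraries. Such values cannot be separated from a difference of the pool 2 libraries. The call was lost without control replicate 2 (adjusted p = 0.178) and without agonist replicate 3 (median -0.10, adjusted p = 0.446), and with total counts only (0.0549) or no filter (0.0620). Heat shock and unfolded protein response genes were called higher with a median of 0.11 over 28 members (camera adjusted p = 0.0496, adjusted p = 0.831 with an estimated correlation), 0.06 in pool 2 and -0.0026 in pool 3. Among them Herpud1 had a log2 fold change of 0.93 (SE 0.40), with 1.73 in pool 2 and 0.18 in pool 3, and Hsph1 one of 0.91 (SE 0.39), with 1.69 and 0.21, to which the same limit applies. That call was lost without control replicate 2 (adjusted p = 0.122), without control replicate 3 (adjusted p = 0.0735) and without agonist replicate 2 (median -0.02, adjusted p = 0.716). It was also lost with total counts only (adjusted p = 0.0724), no filter (0.0663), the stricter filter without and with the block (0.107 and 0.118) and camera on log2 CPM (0.101).

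The other lists of dendritic cell function were not called. The median was 0.03 for maturation and migration genes (adjusted p = 0.284), 0.06 for inflammatory cytokines and chemokines (0.322), -0.27 for interferon-stimulated genes (0.426), -0.17 for MHC class II (0.659) and -0.08 for MHC class I presentation (0.351, mean 0.14). For ligands of T cell inhibitory receptors it was 0.02 (adjusted p = 0.666), for tolerance and retinoic acid metabolism 0.15 (0.139) and for immediate-early and CREB-responsive genes 0.12 (0.0816). Aldh1a2, the enzyme that makes retinoic acid in intestinal dendritic cells, had a log2 fold change of 1.08 (SE 0.45), with 1.94 in pool 2 and 0.12 in pool 3. Arg1, arginase, had one of 1.78 (SE 0.59), with 1.93 and 1.63, at 0.712 to 4.30 CPM. The interferon list had medians of -0.65 in pool 2 and 0.38 in pool 3, opposite in direction. Metabolic and growth lists were not called either: apoptosis and p53 targets had a median of 0.03, glycolysis -0.03, nuclear-encoded oxidative phosphorylation -0.05, cholesterol and fatty acid synthesis 0.04, fatty acid oxidation 0.02, cell cycle 0.07, ribosomal proteins -0.20 and mitochondrially encoded genes 0.12. Over all 30 lists the median and mean differed in sign in 8, those of IL-12 and IL-27, MHC class I, glycolysis, oxidative phosphorylation, cDC2, monocytes and macrophages, plasma cells, and stromal and endothelial cells.

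**Figure D2:**
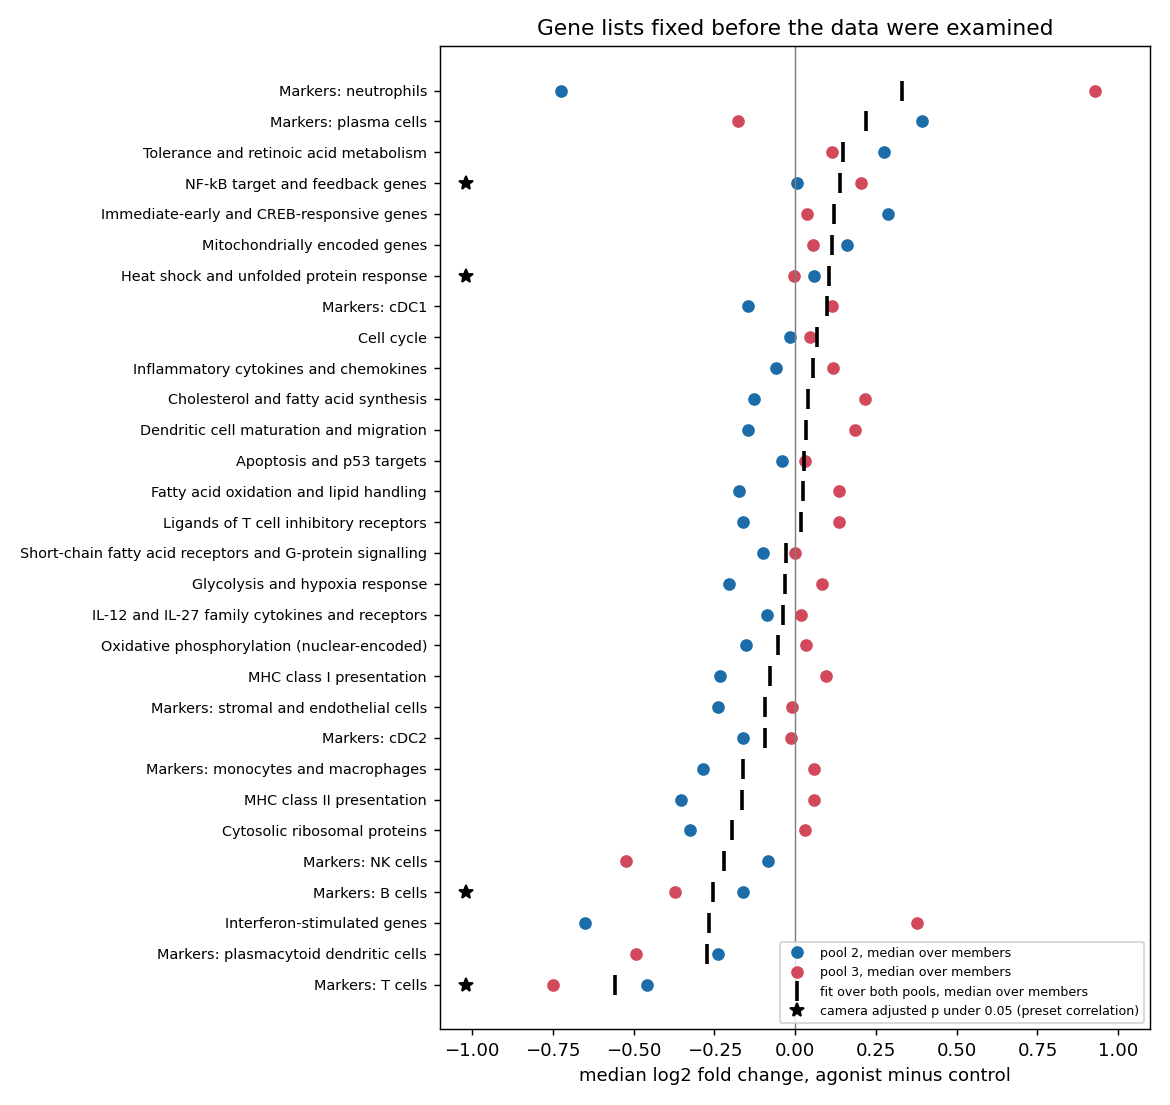
Median log2 fold change (agonist minus control) of the tested members of each of 30 gene lists, as the difference within pool 2, within pool 3 and in the fit over both pools, with a star for lists past camera's threshold at the preset correlation. The T cell list had medians of -0.46 in pool 2 and -0.75 in pool 3, and the interferon list -0.65 and 0.38.

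The pools of cells differed from each other more than the conditions did, by the count of genes. With group as a covariate, 72 genes differed between pool 3 and pool 2 in edgeR's test (19 higher and 53 lower in pool 3; 2536 at an unadjusted p under 0.05). This sets 1 pool against 1 pool with 2 wells of each, so its p-values cover the spread between wells of the same cells and not that between pools or mice. The count depended on the setting, with 5 genes without composition scaling, 8 with a stricter filter and 706 in DESeq2. Sex-linked genes led: Xist, the transcript that silences an X chromosome, had 17776 and 21194 reads in the libraries of pool 2 and 0 in those of pool 3, at least 14820-fold higher on the TMM scale with a floor of 3 counts over the pool. Ddx3y, on the Y chromosome, had 18752 and 21461 reads in pool 3 and 0 in pool 2, at least 11750-fold higher. By these genes pool 2 came from female and pool 3 from male mice, which the labels do not state. The other differences between the pools therefore cannot be separated from sex. Other genes called lower in pool 3 were the chemokine gene Ccl4 (log2 difference -2.89, SE 0.28), the activation marker Cd69 (-2.44, SE 0.27), the urokinase receptor Plaur (-2.53, SE 0.28), the immediate-early gene Nr4a1 (-1.89, SE 0.27), the interferon-stimulated gene Mx2 (-2.26, SE 0.35) and Ighd, the IgD constant region (-1.63, SE 0.24). Ido2, a tryptophan-degrading enzyme, was higher (1.85, SE 0.28).

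Of the 30 lists, 13 differed between the pools by camera (7 higher and 6 lower in pool 3), 0 of them with an estimated correlation (adjusted p = 0.734 or more), a test that could hardly pass with so few libraries. The p-values of camera at the preset correlation rest mainly on the spread between genes and not on that between wells or pools. The values below also come from repeat wells of 1 pool per arm and cannot be separated from the sex of the mice. T cell markers were lower in pool 3 with a median of -0.96 (adjusted p = 1.24e-12; 14 of 20 lower adjusted over the list alone, such as Cd3e at -1.36 and Cd8a at -1.24), and B cell markers with a median of -0.69 (adjusted p = 7.19e-09; 8 of 17). Immediate-early genes were lower with a median of -0.56 (adjusted p = 5.84e-07; 10 of 31, such as Fos at -1.22 and Egr1 at -1.79), and interferon-stimulated genes with a median of -0.75 (adjusted p = 1.34e-06; 9 of 30, such as Ifit1 at -1.90 and Ifit3 at -2.87). Markers of plasmacytoid dendritic cells (median -0.69, adjusted p = 0.000522) and ribosomal protein genes (-0.37, adjusted p = 8.68e-05) were lower as well. Higher in pool 3 were genes of dendritic cell maturation and migration (median 0.42, adjusted p = 0.00186), the cell cycle (0.47, adjusted p = 0.000375), MHC class I (0.36), cDC1 markers (0.37), apoptosis (0.27), cholesterol synthesis (0.19) and fatty acid oxidation (0.26), the last 5 with adjusted p values of 0.0268 to 0.0437.

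The agonist differences of the pools did not follow each other across genes. The log2 differences of pool 2 and pool 3 had a Pearson r of 0.00692 and a Spearman rho of 0.0109 across 18297 genes, which are not independent replicates, and 48.9% of genes had the same sign in both. Among 4757 genes with an average log2 CPM of at least 5, the SD of the differences was 0.53 in pool 2 and 0.22 in pool 3. Of 1542 genes with an average log2 CPM of at least 7, 75 were more than 1 log2 unit higher and 2 more than 1 lower in agonist replicate 2 than in control replicate 2, against 0 and 4 in pool 3. The ferritin heavy chain gene Fth1 (log2 difference 2.43 in pool 2 and 0.05 in pool 3), the actin-binding Pfn1 (2.25 and 0.06) and H2-D1 (2.08 and 0.04) were among the 75.

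**Figure D3:**
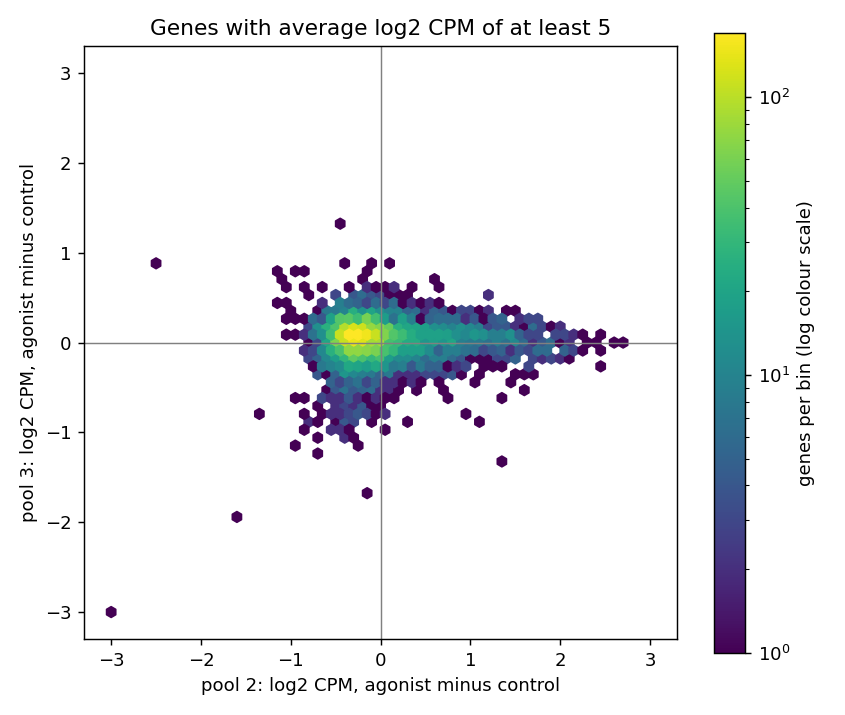
Log2 CPM difference, agonist minus control, in pool 2 (horizontal axis) and pool 3 (vertical axis) for 4757 genes with an average log2 CPM of at least 5, as the number of genes per hexagon on a log colour scale, with values beyond 3 placed at the edge. The differences spread along the pool 2 axis (SD 0.53) more than along the pool 3 axis (SD 0.22), with a tail of higher genes in pool 2.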

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

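Robust dispersion was added after the data were seen; the other alternatives were planned. Where a setting changed a value below, the cause was not tested, except that leaving out a library leaves 1 library in a group, which is then assumed to vary like the remaining pair. It also leaves the pools unequal between the groups, so the differences between the pools (T cell list -0.96, B cell list -0.69) enter those values. The count of genes past the threshold was 0 with every other scaling, limma-voom, the stricter filter, an adjusted p of 0.1, a fold of at least 1.2 and robust dispersion. It was 7 with DESeq2, 9 with no filter, 1 with the replicate block, 6 with the block in DESeq2, 1 with the block and robust dispersion, and 0 to 2 when each library was left out. In edgeR the block changed no other call among the 68 genes below, and in DESeq2 it ended the call of Mcpt4.

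Of 68 genes named for the agonist comparison, 64 kept their direction in every setting run and 4 turned only when a library was left out. Over the left-out libraries the log2 fold change ran from -0.0012 to 0.25 for Il27, -1.58 to 0.046 for Pax5, -0.032 to 1.74 for Tgfb1 and -1.09 to 0.014 for Siglech. Il27 was below the stricter filter and has no value there. Mpeg1 ran from -1.22 to -0.43 and Trac from -1.48 to -0.17. Ebi3 ran from 0.03 to 0.59 and passed in no setting, and Jchain and Igha passed in some.

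The number of lists called, 4, was 1 with total counts only, 1 with no filter, 7 with the replicate block, 0 with an estimated correlation, 0 with fry and 2 to 12 over the left-out libraries. The median of the B cell list ran from -0.77 to -0.024 over the left-out libraries, with the test turning direction in 2 of them. The T cell list kept its direction in every setting and was past the threshold in all but the 2 left-out libraries named in the report, the estimated correlation and fry. The 72 genes differing between the pools became 659 with upper-quartile factors, 5 with total counts only, 706 with DESeq2, 275 with limma-voom, 600 with no filter and 8 with the stricter filter. The correlation of the pools' fold changes was 0.0223 for genes with an average log2 CPM of at least 5. The biological coefficient of variation was 47.6%, and 38.3% with the block.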

Other observations

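The genes in this paragraph were chosen after their values were seen, and they stand for no tested group. Mcpt4, a mast cell protease, had 0 reads in both control libraries and 189 and 38 reads in the agonist libraries, and Mcpt1, a mucosal mast cell protease, had 36 and 0 against 168 and 78. Cpa3, mast cell carboxypeptidase, had 24 and 30 reads in the control libraries and 159 and 22 in the agonist libraries, higher in pool 2 and lower in pool 3. Retnla, a secreted product of alternatively activated macrophages, had 0 and 9 reads against 115 and 166. Besides Igha, the antibody constant regions went both ways. Ighg3 had a log2 fold change of 0.89 (SE 0.32), Igkc one of -1.11 (SE 0.40), Ighm -0.25 (SE 0.33) and Ighd 0.05 (SE 0.68). Ighg1 had 85 and 2725 reads in the control libraries and 37 and 19 in the agonist libraries, and Ighg2b differed by -2.45 in pool 2 and 0.87 in pool 3. Apart from Igha with the block, none of these genes passed in the edgeR test of all 4 libraries with its default filter, while Igha, Mcpt4, Ighg1 and the mast cell tryptase gene Tpsab1 were among those passing with no filter, Ighg1 passed without control replicate 2, and DESeq2 called Mcpt4 and Retnla.

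The tests of plasma cell genes, of thinning, and of GC content and length were chosen after the result was seen. Some were also changed after values were known: plasma cell genes were first a smaller set, all 7 of whose tested members were higher, and thinning replaced a comparison with Poisson counting error that had also argued against that explanation. Tests of the T cell list against the B cell list and between the pools were run and dropped, since neither measures the spread between wells of a pool.

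T cell marker genes were lower in the agonist wells of both pools. Less T cell RNA in the agonist wells was tested with a second list of 26 T cell genes that shares none with the first. That list was lower too (median -0.50, 21 of 26 lower in both pools). It marks the same cells in the same libraries, so its fall extends the pattern to more genes and does not tell causes apart. The T cell median lay below the B cell median by 0.30 in pool 2 and by 0.38 in pool 3, without a spread between wells to set this against. A loss of all other cell types alike, uneven division of T cells between the wells of a pool and an effect of the agonist on T cells stay open, since each pool had 1 well per condition.

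Igha and Jchain were lower in the agonist well of both pools. Fewer plasma cells in those wells cannot be told apart from other causes, since the other 10 tested members of the plasma cell list went both ways (median log2 fold change 0.28) and several are near the floor or also expressed by other cells. Of the 10, 1 was lower in both pools, and the lowest, Eaf2 at -0.85, differed by 0.08 in pool 2 and -1.62 in pool 3. Uneven capture of a few antibody-secreting clones was tested by the spread of 17 variable segments (8 lower and 4 higher in both pools). Their log2 fold changes had an SD 6.46 times that of 5289 other genes, which were matched only by the limits of the expression range. Uneven capture is a candidate explanation for this spread, but other causes could widen it too, so the ratio does not tell causes apart. The median of the segments was -1.30, a net fall that uneven capture does not by itself predict. Fewer antibody-secreting cells and an effect of the agonist on IgA transcripts stay open.

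The libraries of pool 2 differed from each other more than those of pool 3. Counting error is argued against, since pool 3 thinned to the depth of pool 2 kept an SD of 0.415 times that of pool 2, and GC content and transcript length explained 5.09% of the variance of the pool 2 differences. Uneven amplification of few input molecules cannot be told apart from other causes with 1 well per condition in a pool. The SD at an average log2 CPM of 9 or more was 0.743 times that at 4 to 6 in pool 2, between the limits set for this test. It was 0.525 times in pool 3, a comparison for which no criterion was set, so no conclusion is drawn from it. A response to the agonist in pool 2 alone, or one that depends on the sex of the mice, stays open and was not tested, since each pool had 1 well per condition.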
